A study of Mus musculus with 16 samples.

How the data were processed

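Total RNA had been isolated with a fibrous tissue kit from the left ventricles of 16 male mice, labelled with biotin and hybridized to single-colour Illumina mouse arrays, 1 per heart, per the labels. The series gave 2 tables of values. The deposited intensity table holds 1 intensity per probe and array for 25697 probes, the mean signal of the beads, from which the authors had already subtracted background, since 14378 probes lie below 0 on at least 1 array. Beside each signal stands a detection p-value deposited by the authors, which compares the probe with the negative control beads of its array. The deposited series matrix holds the same intensity values on the linear scale, multiplied by the authors by 1 factor per array so that all 16 arrays have a mean of 276; the largest departure from 1 factor per array was 0.0158. The submitters' processing notes name BeadStudio and GenomeStudio without versions or steps. The array mean of the deposited signal ran from 129 to 375, and the number of arrays limits the precision of each value.

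Samples were grouped by the genotype in their labels into control, TRAF2LC, IkBaDN and double transgenic, 4 arrays each, and the replicate numbers of the titles name single arrays. The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where stated. Gene symbols came from the probe table of the series. Of the probes, 23978 have 1 symbol and 1719 are unnamed here, and 23962 were matched by RefSeq gene number to the mouse RefSeq table of assembly GRCm38.p6, which changed 0 symbols.

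The intensity table was corrected with the nec step of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values, with an offset of 16. The arrays were quantile normalized and put on the log2 scale. Probes with a detection p under 0.01 on at least 4 of the 16 arrays, whatever their genotype, were tested: 9449 probes, 517 of them unnamed, for 6902 genes. All 16 arrays entered 1 limma fit of the 4 genotype means with empirical Bayes moderation (12 residual and 4.64 prior degrees of freedom). Each genotype with a transgene was compared with control, double transgenic hearts with each single transgenic genotype, and the interaction was the difference of both effects of 1 transgene. Probes with a two-sided p adjusted by Benjamini-Hochberg under 0.05 within a comparison are called. Fold changes are ratios of geometric means, and errors of log2 changes are limma standard errors. These errors pool the spread of all 4 genotypes, so they may be too small where a compared genotype spreads more than the others. Where a probe was detected on 0 arrays of a group, that group was set to the detection limit of each array and the change is given as at least that large. Where 2 such groups enter a value, only its p is given. Named probes detected on some arrays of a compared group keep their measured values: Ifit2 and Cyp2b10 on 1 control array, Birc5 and Map3k14 on 2 control arrays and Isg15 and Krt222 on 3, Aqp4 on 2 and Kcnv2 on 3 TRAF2LC arrays, Relb and Map3k14 on 2 and Usp18, Traf2, Camk2b, Ppm1e and Myot on 3 IkBaDN arrays, and Traf2, Bcl2 and Myot on 3 double transgenic arrays.

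Genes named are Traf2, Nfkbia, Myh6, Nfkb2 and Relb, and further the 10 called genes with the largest increase and the 10 with the largest decrease in each comparison with control and in double transgenic against IkBaDN hearts, and 5 each way in double transgenic against TRAF2LC and in the interaction. Outside the interaction the values of the compared groups also had to have no overlap, which chance gives for 2.86% of genes. From each list up to 4 called members with the smallest p are named, or, where none passed, the member with the smallest p. A gene is given by its brightest tested probe, and other tested probes are given where they differ in direction or call. Symbols of predicted genes were counted but not named, and the unnamed probe of the interaction was singled out after its values were seen.

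Of 42 gene lists, the 31 with at least 5 measured genes were tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the lists of that comparison. The test was repeated with an estimated correlation and with fry, which asks whether a list moves 1 way on balance and compares it with no other genes. Of 186 pairs of list and comparison 29 were called. Of these 3 were called with the estimated correlation (the fetal programme and cell cycle lists in TRAF2LC against control and the fetal programme list in double transgenic against TRAF2LC) and 11 with fry, which called 15 in all. Median, mean and test differed in sign in 28 pairs, 0 of them called. With members below the detection limit at their bound, run for the 21 called lists outside the interaction, the median that moved most was that of the cell cycle list in TRAF2LC against control, 0.34 against 0.39. For effects with and without the other transgene, correlations ran over probes, and their p came from all regroupings of the arrays within both comparisons. Overlaps of calls that share arrays were set beside 100 simulations of groups without effect and beside splits of the shared arrays. The simulations drew independent noise with 1 SD per probe in all groups. They counted as many probes of smallest p as were called in the data.

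The fit and the list test were tested on simulated log2 values of the same size, with independent noise and 1 SD per probe in all groups. Background correction, normalization and the filter were not tested. Of 50 probes changed 2-fold, between 88% and 94% were recovered in the 5 comparisons of groups and 70% in the interaction, and of 50 changed 1.5-fold, between 44% and 64% and 28%. Between 2.75% and 8.06% of the calls were false. Of 10 lists moved by 0.5 on the log2 scale 10 were called, and of 90 unmoved lists 0. These lists held random genes with independent noise, so they do not show how the test treats lists whose genes vary together.

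Alternatives were other background corrections (normexp with an offset of 50, and none), median scaling, cyclic loess, the authors' scaled values, no filter, detection on all 16 arrays, trended and robust moderation, array weights, a fit of the compared groups alone, blocks of replicate number and of runs of the P numbers in the labels, a threshold of 1.5-fold, the mean over the probes of a gene, and each array left out in turn. The first and last 8 columns of the deposited table as a block, and the fit without the 2 arrays of lowest weight, were chosen after the data were seen. The slide of each array is not given in the sources used here. Figures were drawn with matplotlib 3.10.9.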

Results

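Gene expression was measured in the left ventricle of male mice of 4 genotypes, with 4 hearts per genotype and 1 single-colour Illumina array per heart. Littermate controls were set beside mice with a TRAF2 transgene (TRAF2LC), mice with an altered IkBa transgene (IkBaDN) and mice with both transgenes (double transgenic). Both transgenes carry the name of Myh6, the gene of the alpha myosin heavy chain, whose promoter is commonly used to drive expression in cardiomyocytes. TRAF2 is an adapter protein of TNF receptors, and IkBa holds NF-kB dimers in the cytoplasm. The title of the series concerns protection of the heart by TRAF2 and the non-canonical branch of NF-kB signalling. The mean deposited signal per array ran from 129 to 375, and between 7948 and 9397 of the 25697 probes were detected. The lowest signals were those of IkBaDN replicates 2 and 3 (129 and 204), which also had the fewest probes detected (7948 and 8192). Their detection limits were the highest, 5.81 and 5.73 on the log2 scale, which bears on genes detected on 0 IkBaDN arrays. TRAF2LC replicate 4 had the most probes detected, 9397. Over the 9449 probes tested, the correlation between 2 arrays lay between 0.954 and 0.990. The number of arrays limits the precision of each value.

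The genes of the transgenes and of the NF-kB pathway were examined first. Traf2 had a mean log2 intensity of 5.85 ± 0.18 in control, 6.11 ± 0.24 in TRAF2LC, 5.85 ± 0.12 in IkBaDN and 5.70 ± 0.22 in double transgenic hearts (SD, n = 4 each). Its probe was detected on 14 of the 16 arrays. Nfkbia, the gene of IkBa, stood at 8.31 ± 0.19, 8.67 ± 0.13, 8.36 ± 0.24 and 8.32 ± 0.14 in the same order. Where these probes lie relative to the transgenes is not given in the sources used here, so they check no genotype label. The brighter probe of Myh6 had means of 14.37 ± 0.03, 14.43 ± 0.08, 14.36 ± 0.05 and 14.39 ± 0.10, and its dimmer probe means of 8.31, 8.06, 8.11 and 8.51. The probes of Nfkb2, Xist, Eif2s3y, Kdm5d and Uty were detected on 0 arrays, so the sex labels could not be checked. Relb, an NF-kB subunit of the non-canonical branch whose gene is itself an NF-kB target, had means of 6.49 ± 0.37 in control, 7.69 ± 0.35 in TRAF2LC, 5.63 ± 0.32 in IkBaDN and 5.91 ± 0.19 in double transgenic hearts.

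Hearts with the TRAF2 transgene alone were compared with control hearts to ask what the adapter changes by itself. Interferon-induced genes and Myh7, the beta myosin heavy chain of the fetal ventricle, showed the largest increases among named genes. Ifit3 rose 6.70-fold (log2 change 2.75 ± 0.45, SE, n = 4 per genotype, adjusted p = 0.00492). Myh7 rose 6.02-fold (log2 change 2.59 ± 0.39, adjusted p = 0.00271). Tsc22d4, a member of the TSC22 domain family, rose 5.50-fold (log2 change 2.46 ± 0.17, adjusted p = 4.57e-07). Relb rose 2.30-fold (log2 change 1.20 ± 0.20, adjusted p = 0.00648). Tnip1, which encodes a partner of the NF-kB inhibitor A20, rose 2.45-fold (log2 change 1.29 ± 0.19, adjusted p = 0.002). Dlg2, a scaffold protein of the membrane-associated guanylate kinase family, was detected on 0 control arrays and was at least 2.57-fold higher (adjusted p = 3.72e-06).

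Of the 20 measured interferon response genes, 20 were higher in TRAF2LC and 7 rose over all genes tested, while adjusted over the list alone 15 rose. The median log2 change of the list was 0.93, and 0.60 without TRAF2LC replicate 4 (adjusted p = 3.62e-18; adjusted p = 0.101 with an estimated correlation). Usp18, which removes ISG15 from proteins, rose by 2.49 ± 0.41 on the log2 scale (adjusted p = 0.0049) and Isg15 itself by 2.47 ± 0.52 (adjusted p = 0.0303). Rsad2, the antiviral viperin, rose by 1.84 ± 0.39 (adjusted p = 0.0317) and Ifit2, detected on 1 control array, by 2.24 ± 0.51 (adjusted p = 0.0474). Irf7, a transcription factor of the interferon response, was detected on 0 control arrays and was at least 2.03-fold higher (adjusted p = 0.0379). The SEs come from the fit of all 4 genotypes, but these genes spread more in TRAF2LC hearts. SDs in TRAF2LC against control were 1.271 and 0.106 for Usp18, 1.498 and 0.466 for Isg15 and 1.349 and 0.219 for Ifit3. Their errors and p values may therefore be too small. With these 2 genotypes fitted alone, Ifit3, Usp18, Isg15, Rsad2, Ifit2 and Irf7 were not called (adjusted p between 0.0727 and 0.201). On the single arrays the list median over the control mean was 0.67, 0.77, 0.59 and 2.24 in TRAF2LC replicates 1 to 4, and at most 0.05 in controls. All 11 measured macrophage markers were higher too, with a median of 0.40, and 0.22 without TRAF2LC replicate 4 (adjusted p = 1.90e-06; adjusted p = 0.0981 with an estimated correlation). Among them Cx3cr1, the fractalkine receptor, rose by 0.85 ± 0.17 (adjusted p = 0.0255), and adjusted over the list alone 2 rose. TRAF2LC replicate 4 also had the highest macrophage median, 0.93, against 0.12 to 0.26 on the other 3 arrays. Antigen presentation genes were higher in 16 of 16 cases (median 0.44, adjusted p = 1.25e-06; adjusted p = 0.24 with an estimated correlation). Their medians on TRAF2LC replicates 1 to 4 were 0.16, 0.33, 0.27 and 1.27, and without replicate 4 the median change was 0.22. None of these passed over all genes tested and 5 rose adjusted over the list alone. The member with the smallest p, the peptide transporter Tap1, was detected on 0 control arrays and stood at least 1.48-fold higher, which did not pass (adjusted p = 0.0956).

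Canonical NF-kB targets rose as a list, with 10 of 13 members higher and a median of 0.32, and 0.08 without TRAF2LC replicate 4 (adjusted p = 1.68e-04; adjusted p = 0.0774 with an estimated correlation). Tnip1 and Relb rose over all genes tested and 3 members rose adjusted over the list alone. The list of the fetal gene programme and hypertrophy rose with a median of 0.48 (adjusted p = 2.18e-04; adjusted p = 0.0193 with an estimated correlation). Its 14 members held 11 higher values, of which Myh7 passed over all genes tested, and adjusted over the list alone 8 rose and 1 fell. Cell cycle genes had a median of 0.39 with 10 of 12 higher (adjusted p = 6.06e-05; adjusted p = 0.0193 with an estimated correlation). None of them passed over all genes tested, 6 rose and 1 fell adjusted over the list alone, and Birc5, the inhibitor of apoptosis survivin, stood at 0.78 ± 0.19 (adjusted p = 0.0743). Genes of the extracellular matrix were higher in 20 of 23 cases (median 0.24, adjusted p = 3.94e-05; adjusted p = 0.101 with an estimated correlation). Within that list the growth factor gene Tgfb3 rose by 1.14 ± 0.20 (adjusted p = 0.00648) and Thbs2, a matrix glycoprotein, fell (log2 change -0.50 ± 0.10, adjusted p = 0.0199), and adjusted over the list alone 8 rose and 1 fell.

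Fatty acid oxidation genes fell as a list, 20 of 24 being lower (median -0.22, -0.08 without TRAF2LC replicate 4, adjusted p = 1.68e-04; adjusted p = 0.318 with an estimated correlation). On the single arrays the list median was -0.20, 0.03, 0.01 and -0.73 in TRAF2LC replicates 1 to 4, and between -0.04 and 0.09 in controls. Acot1, an acyl-CoA thioesterase, was the 1 member that fell both over all genes and adjusted over the list alone (log2 change -1.14 ± 0.20, adjusted p = 0.00853). Calcium handling and ion channel genes had a median of -0.18 with 19 of 23 lower, and of -0.07 without TRAF2LC replicate 4, -0.11 without control replicate 3 and -0.11 without control replicate 4 (adjusted p = 0.0128; adjusted p = 0.24 with an estimated correlation). The single TRAF2LC arrays stood at -0.16, -0.02, -0.04 and -0.48. Kcnv2, a modifying subunit of potassium channels, was the 1 member that fell by either count (log2 change -0.92 ± 0.21, adjusted p = 0.0483). Oxidative phosphorylation genes had a median of -0.12 with 28 of 35 lower, and of -0.05 without TRAF2LC replicate 4 (adjusted p = 0.0271; adjusted p = 0.462 with an estimated correlation). Of its members 0 passed over all genes or adjusted over the list alone. Aqp4, a water channel, fell (log2 change -0.88 ± 0.20, adjusted p = 0.0474). So did Ttll1, Tbc1d10c, Ano10, Cmtm8, Lypd2, Rgs7bp and Ces1d, with log2 changes between -1.33 and -0.85. The chemokine gene Ccl11 also fell (-0.70 ± 0.16, adjusted p = 0.041). Pde1b, a calmodulin-dependent phosphodiesterase, rose 3.67-fold (adjusted p = 0.00122), Bcl2, an inhibitor of apoptosis, by 0.99 ± 0.21 (adjusted p = 0.0343) and the ribosomal protein gene Rpl3 by 0.50 ± 0.11 (adjusted p = 0.0333). The second probes of Ttll1 and Ccl11 and 1 of 3 other probes of Tnip1 did not pass (log2 changes of -0.96 for Ttll1 and 0.15 for Tnip1, that of Ccl11 being detected on 0 TRAF2LC arrays).

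In all, 98 of 9449 probes were called in TRAF2LC against control, 70 higher and 28 lower, for 82 named genes and 9 unnamed probes. Median scaling called 70 probes, 67 higher and 3 lower, and the authors' scaled values 79, 70 higher and 9 lower. With the first and last 8 columns of the deposited table as a block, 118 were called, the 98 among them, and each of the 98 kept its sign within both column sets. Each genotype has 2 arrays in each set, so this block leaves every log2 change as it was and only takes up spread. The signs were read on the same arrays that gave the calls, so they could hardly differ. Neither count is separate support, here or in the comparisons below. Without 1 array the count was 48, 40, 51 and 61 for control replicates 1 to 4, 61 for TRAF2LC replicate 2 and 50 for TRAF2LC replicate 4, and it was 38 without background correction, 54 without a filter, 60 with detection on all 16 arrays, 35 with these 2 genotypes fitted alone, where Ifit3 (adjusted p = 0.0727), Usp18 (0.0856), Cmtm8 (0.0859) and Acot1 (0.0930) were not called, and 57 without the 2 arrays of lowest weight, TRAF2LC replicate 4 and IkBaDN replicate 2. Of 28 named calls 12 held without any single array, and calls lost without at least 1 array, with the highest adjusted p, were those of Ttll1 (0.166), Kcnv2 (0.16), Aqp4 (0.174), Ifit2 (0.141), Ccl11 (0.155), Ces1d (0.137), Irf7 (0.119), Bcl2 (0.122), Lypd2 (0.119), Rgs7bp (0.0872), Cx3cr1 (0.104), Rpl3 (0.133), Isg15 (0.104), Rsad2 (0.106), Thbs2 (0.0838) and Tbc1d10c (0.0628), those of Ano10 (0.0764) and Cmtm8 (0.0590) with median scaling and of Relb (0.0606) without background correction, and those of the oxidative phosphorylation list without control replicate 3 (adjusted p = 0.0920) or TRAF2LC replicate 4 (0.446) and the calcium handling list without TRAF2LC replicate 4 (0.172).

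**Figure D1:**
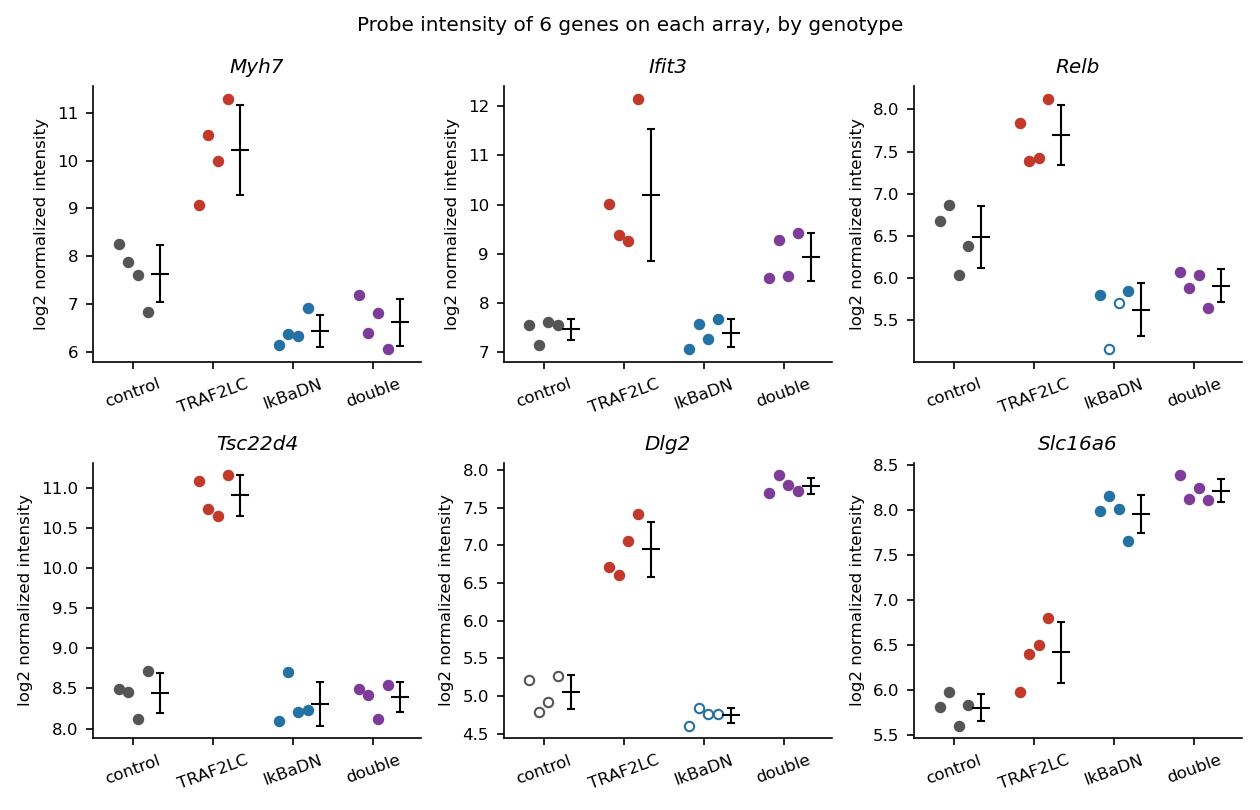
Log2 normalized intensity of 1 probe each of Myh7, Ifit3, Relb, Tsc22d4, Dlg2 and Slc16a6 on the 16 arrays, by genotype; each point is 1 array (open where its detection p was not under 0.01), and the bar beside each group is the mean ± SD (n = 4). Myh7 stood at 10.23 ± 0.94 in TRAF2LC against 7.64 ± 0.60 in control and 6.61 ± 0.50 in double transgenic hearts, and Slc16a6 at 7.95 ± 0.21 in IkBaDN against 5.80 ± 0.15 in control.

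Hearts with the IkBa transgene alone were compared with control hearts to ask what the altered IkBa changes by itself. Slc16a6, of the monocarboxylate transporter family, rose 4.44-fold (log2 change 2.15 ± 0.16, SE, n = 4 per genotype, adjusted p = 7.09e-07). Kcne1, a subunit of the slow delayed rectifier potassium channel, rose 3.84-fold (log2 change 1.94 ± 0.14, adjusted p = 7.43e-07). Fam122b rose 3.72-fold (log2 change 1.90 ± 0.13, adjusted p = 7.05e-07) and Slc17a7, a vesicular glutamate transporter, 2.91-fold (log2 change 1.54 ± 0.18, adjusted p = 1.89e-04). Genes that fell included the myosin light chain gene Myl1 (log2 change -1.58 ± 0.16, adjusted p = 4.31e-05), Tmod4, a tropomodulin that caps thin filaments (-1.33 ± 0.18, adjusted p = 9.01e-04, all 3 probes called), and Myot, the Z-disc protein myotilin (-1.07 ± 0.21, adjusted p = 0.0318). Relb stood at -0.86 ± 0.20 (adjusted p = 0.0919), which did not pass. It did pass with the runs of the P numbers as a fixed block (adjusted p = 0.00279) or a random one (0.0294), and with the first and last 8 columns of the table as a block (0.0219).

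Other increases were those of the cytochrome P450 gene Cyp2b10 (3.08-fold, adjusted p = 9.09e-04, detected on 1 control array), the growth factor midkine, Mdk (2.40-fold, adjusted p = 1.89e-04), the heme-binding protein gene Hebp1 (2.36-fold, adjusted p = 2.58e-04), the G protein subunit gene Gnb3 (2.05-fold) and Urah (1.99-fold). A second probe of Mdk stood at 0.88 and did not pass. Lad1 was detected on 0 control arrays and was at least 2.45-fold higher (adjusted p = 1.38e-05). Decreases were found for Cds1, an enzyme of phosphatidylinositol synthesis (-1.35 ± 0.19, adjusted p = 9.09e-04), the kinase subunit gene Camk2b (-1.22 ± 0.25, adjusted p = 0.0413), Ddah1, Ppm1e and Adamtsl4, the last 3 with log2 changes of -0.91, -0.78 and -0.69. Cep85 and Krt222 were detected on 0 IkBaDN arrays and were at least 1.28-fold and 1.02-fold lower (adjusted p = 0.0168 and 0.0427). Of the 31 gene lists tested, the markers of atrial cardiomyocytes fell, 9 of 10 being lower (median -0.32, adjusted p = 1.37e-04; adjusted p = 0.649 with an estimated correlation). Myl1 fell over all genes tested, and 3 members fell adjusted over the list alone. The lowest adjusted p of the other 30 lists was 0.189, for antigen presentation, so no NF-kB list was called. Myh7 had a log2 change of -1.19 ± 0.39 (adjusted p = 0.32).

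A total of 42 probes were called in IkBaDN against control, 24 higher and 18 lower (7 and 11 of the 18 called with median scaling, 18 and 15 of the 33 with the authors' scaled values), for 36 named genes and 3 unnamed probes. With the column sets as a block 61 were called, the 42 among them, and each of the 42 kept its sign within both sets. The count was 24, 24 and 21 without control replicates 2, 3 and 4, 18 with median scaling, where Mdk (adjusted p = 0.0633), Hebp1 (0.136), Gnb3 (0.397) and Urah (0.414) were not called, 65 with array weights and 24 with these 2 genotypes fitted alone, and 13 of 20 named calls held without any single array. The calls lost without at least 1 array, with the highest adjusted p, were those of Adamtsl4 (0.149), Camk2b (0.139), Krt222 (0.139), Ppm1e (0.138), Myot (0.116), Cep85 (0.0738) and Ddah1 (0.0582).

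Hearts with both transgenes were then compared with control hearts. Dlg2 was detected on 0 control arrays and was at least 4.61-fold higher in double transgenic hearts (adjusted p = 3.74e-08, n = 4 per genotype). Slc16a6 rose 5.34-fold (log2 change 2.42 ± 0.16, SE, adjusted p = 1.17e-07), Cyp2b10 4.32-fold (2.11 ± 0.22, adjusted p = 5.24e-05, detected on 1 control array), Fam122b 3.95-fold (1.98 ± 0.13, adjusted p = 1.17e-07) and Kcne1 3.30-fold (1.72 ± 0.14, adjusted p = 3.44e-06). Acta2, the smooth muscle alpha actin, rose 2.01-fold (1.01 ± 0.19, adjusted p = 0.0129, all 4 probes called). Camk2b fell (log2 change -1.55 ± 0.25, adjusted p = 0.00465), as did Tmod4 (-1.41 ± 0.18), Myl1 (-1.33 ± 0.16) and Cds1 (-1.30 ± 0.19), with adjusted p between 2.57e-04 and 0.00125 for these 3.

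Slc17a7, Hebp1 and Mdk rose 3.29-fold, 2.35-fold and 2.07-fold, a second probe of Mdk (0.70) not passing, and Lad1 was at least 2.21-fold higher. Genes that fell included Slc40a1, the iron exporter ferroportin (-1.01 ± 0.16, adjusted p = 0.00466), the neurotrophin gene Bdnf (-0.90 ± 0.12, adjusted p = 8.30e-04), Abcb4, Snai3, Myot and Igsf1, the last 4 with log2 changes of -1.02, -1.20, -0.92 and -0.89. Neither of the other 2 probes of Igsf1 passed (-0.32 and -0.81). Cenpa, the centromeric histone, fell (-0.88 ± 0.14, adjusted p = 0.00336), and so did the heat shock protein genes Hspb6 (-0.49 ± 0.11, adjusted p = 0.0442) and Hspa2 (-0.61 ± 0.10, adjusted p = 0.00478), whose second probe stood at -0.02. Extracellular matrix genes rose as a list, 20 of 23 being higher (median 0.17, adjusted p = 0.0184; adjusted p = 0.555 with an estimated correlation). None of its members passed over all genes tested and 1 rose adjusted over the list alone. The interferon response list was not called (adjusted p = 0.0521), and its member with the smallest p, Isg15, stood at 2.02 ± 0.52 (adjusted p = 0.0934). Relb stood at -0.58 ± 0.20 (adjusted p = 0.274) and Map3k14, the kinase of the non-canonical branch known as NIK, at 1.01 ± 0.26 (adjusted p = 0.0974).

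For double transgenic hearts against control 86 probes were called, 48 higher and 38 lower (19 and 7 of the 26 called with median scaling, 49 and 21 of the 70 with the authors' scaled values), for 71 named genes and 8 unnamed probes. With the column sets as a block 129 were called, the 86 among them, and each of the 86 kept its sign within both sets. Of the 42 probes called in IkBaDN against control, 36 were also called here, each in the same direction, where unchanged groups simulated against the shared controls gave 8.30 (at most 15) and independent calls would give 0.194. With the controls split between both comparisons, 14 to 16 probes were called in both over 6 splits, each in the same direction. The correlation of the 2 sets of log2 changes over probes, which are not independent replicates, was 0.619 against 0.50 with no effect, and their covariance was 0.0304 against 0.0179, a difference of 0.0125. Of the 98 probes called in TRAF2LC against control, 3 were called here, 1 in the same direction, against a simulated 13.4 and 0.468 independent calls in the same direction. The count was 45, 46, 46 and 51 without control replicates 1 to 4, 48, 42 and 42 without double transgenic replicates 1, 3 and 4, 26 with median scaling, where Slc40a1 (adjusted p = 0.0929), Bdnf (0.167), Igsf1 (0.459), Hspa2 (0.845) and Cenpa (0.378) were not called, and 168 with array weights, and 18 of 23 named calls held without any single array. Calls lost without at least 1 array, with the highest adjusted p, were those of Snai3 (0.164), Myot (0.181), Hspb6 (0.154), Abcb4 (0.125), Acta2 (0.0576) and the extracellular matrix list without control replicate 1 (0.0521) or double transgenic replicate 4 (0.107).

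Double transgenic hearts were compared with TRAF2LC hearts to see what the IkBa transgene changes where TRAF2 is also present. Myh7 fell 12.2-fold (log2 change -3.61 ± 0.39, SE, n = 4 per genotype, adjusted p = 3.25e-05) and Tsc22d4 5.70-fold (-2.51 ± 0.17, adjusted p = 1.66e-07). The NF-kB genes Relb (-1.78 ± 0.20, adjusted p = 5.25e-05) and Tnip1 (-1.74 ± 0.19, adjusted p = 3.25e-05) fell, and so did Cyld, a deubiquitinase that restrains NF-kB signalling (-0.76 ± 0.15, adjusted p = 0.00782). One of the 3 other probes of Tnip1, detected on 0 double transgenic arrays, did not pass. Fam122b, Slc17a7, Slc16a6 and Kcne1 rose 4.40-fold, 4.38-fold, 3.48-fold and 3.42-fold, with adjusted p of 4.20e-06 or less. Cyp2b10, detected on 0 TRAF2LC arrays, was at least 4.03-fold higher (adjusted p = 1.03e-05).

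Canonical NF-kB targets fell as a list, 12 of 13 being lower (median -0.27, -0.17 without TRAF2LC replicate 4, adjusted p = 1.28e-04; adjusted p = 0.0911 with an estimated correlation). Of its members 2 fell over all genes tested and 5 adjusted over the list alone. All 20 interferon response genes were lower (median -0.74, -0.33 without TRAF2LC replicate 4, adjusted p = 2.38e-08; adjusted p = 0.403 with an estimated correlation). Usp18 fell over all genes tested (-1.79 ± 0.41, adjusted p = 0.0215), its second probe (-1.44) did not pass, and adjusted over the list alone 6 fell. The SD of Usp18 was 1.271 in TRAF2LC and 0.206 in double transgenic hearts, so its pooled SE may be too small. With these 2 genotypes fitted alone Usp18 was not called (adjusted p = 0.110). The 11 macrophage markers were lower throughout (median -0.40, -0.24 without TRAF2LC replicate 4, adjusted p = 4.51e-05; adjusted p = 0.215 with an estimated correlation). Cx3cr1 fell by both counts (-0.69 ± 0.17, adjusted p = 0.0368). Antigen presentation genes were lower in 16 of 16 cases (median -0.38, -0.15 without TRAF2LC replicate 4, adjusted p = 4.51e-05; adjusted p = 0.403 with an estimated correlation). The peptide transporter Tap2 fell (-0.79 ± 0.16, adjusted p = 0.00984), and 4 members fell adjusted over the list alone. The list of the fetal gene programme and hypertrophy fell (median -0.25, -0.39 without TRAF2LC replicate 2, mean -0.64, adjusted p = 4.36e-04; adjusted p = 0.0364 with an estimated correlation). Myh7 and Rcan1, a calcineurin regulator (-0.54 ± 0.13, adjusted p = 0.0252), fell over all genes tested, and adjusted over the list alone 6 fell. Smooth muscle and pericyte markers were higher in 9 of 9 cases (median 0.27, adjusted p = 0.00197; adjusted p = 0.215 with an estimated correlation). Acta2 rose by both counts (0.97 ± 0.19, adjusted p = 0.00638, all 4 probes called).

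Among the other named genes, Vac14, a scaffold of phosphoinositide kinase, fell 3.6-fold (adjusted p = 1.16e-04). Lrp11 and Rnase1 were detected on 0 double transgenic arrays and were at least 2.23-fold and 2.43-fold lower (adjusted p = 3.98e-05 and 1.03e-05). Myl1 (-1.47 ± 0.16), Tgfb3 (-1.13 ± 0.20), Bcl2 (-1.01 ± 0.21), the slow skeletal troponin gene Tnnt1 (-1.01 ± 0.17), Junb (-0.76 ± 0.18), Rpl3 (-0.60 ± 0.11), Hspb6 (-0.59 ± 0.11), Cenpa (-0.54 ± 0.14) and Hspa2 (-0.43 ± 0.10) fell, with adjusted p of 0.0433 or less. Kcnv2 rose (1.16 ± 0.21, adjusted p = 0.00481), as did Acot1 (0.79 ± 0.20, adjusted p = 0.0426) and Ccl11 (0.64 ± 0.16, adjusted p = 0.031). The second probes of Hspa2 (0.14) and Ccl11 (detected on 0 TRAF2LC arrays) did not pass. Traf2 stood at -0.41 ± 0.14 (adjusted p = 0.147) and Nfkbia at -0.35 ± 0.13 (adjusted p = 0.194), so neither passed.

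**Figure D2:**
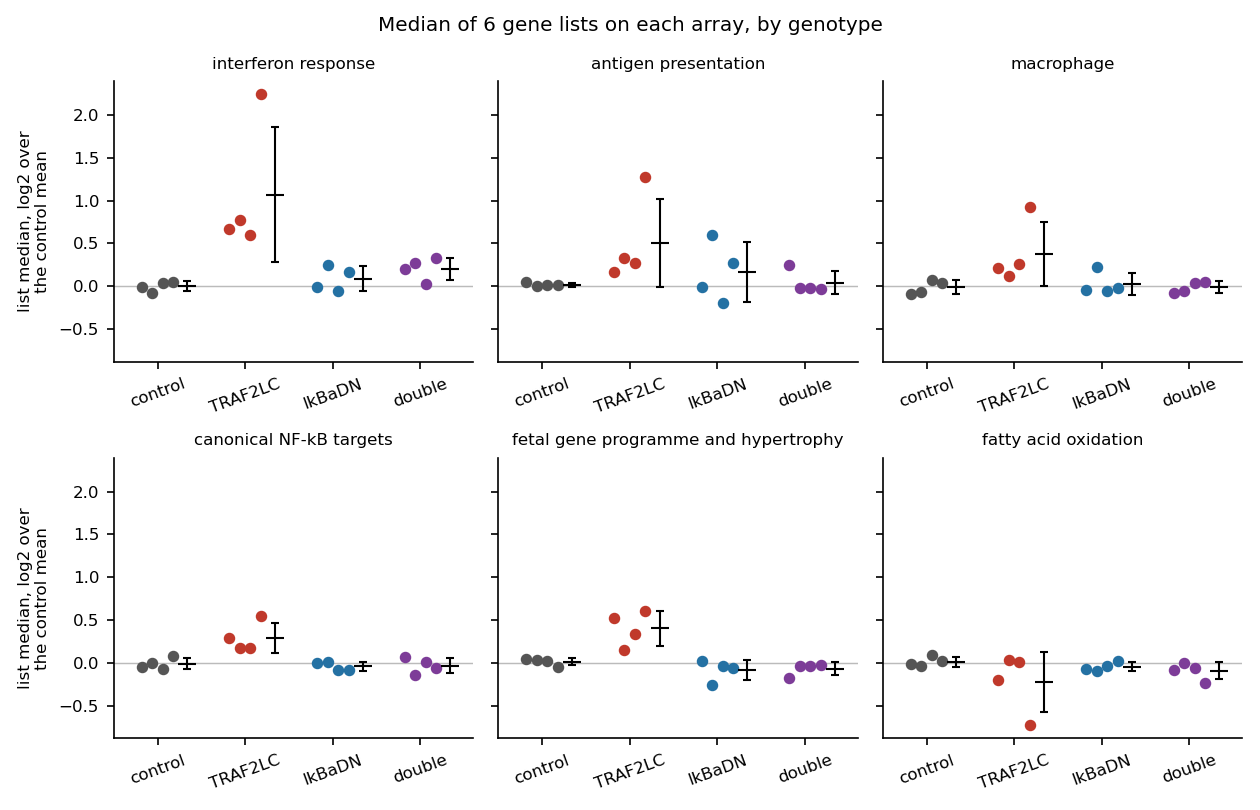
Median over the measured genes of 6 lists on each of the 16 arrays, as log2 over the control mean, by genotype; each point is 1 array and the bar beside each group is the mean ± SD (n = 4). The interferon response list lay between 0.59 and 2.24 in TRAF2LC and between 0.03 and 0.33 in double transgenic hearts.

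Between double transgenic and TRAF2LC hearts 281 probes were called, 130 higher and 151 lower (35 and 85 of the 120 called with median scaling, 57 and 98 of the 155 with these 2 genotypes fitted alone), for 232 named genes and 25 unnamed probes. With the column sets as a block 397 were called, the 281 among them, and each of the 281 kept its sign within both sets. Of the 98 probes called in TRAF2LC against control, 67 were also called here, 66 in the opposite direction (50 up then down, 16 down then up), where unchanged groups simulated around the shared TRAF2LC arrays gave 26.3 (at most 35) and independent calls would give 1.5 in opposite directions. The simulations gave all groups the same SD, while the 98 probes spread more in TRAF2LC (SD 0.36) than in double transgenic hearts (0.05). The simulated 26.3 may therefore be too low. With the TRAF2LC arrays split between both comparisons, 21 to 38 were called in both. Over probes, the correlation of the 2 sets of log2 changes was -0.634 against -0.499 with no effect, and their covariance was -0.0450 against -0.0179, a difference of -0.0271. The count was 184 without double transgenic replicate 3, 120 with median scaling, where Cyld (adjusted p = 0.160), Tap2 (0.119), Hspb6 (0.407) and Rpl3 (0.383) were not called, and 155 with these 2 genotypes fitted alone, where Bcl2 (0.0735) and Tap2 (0.0568) were not, and 22 of 30 named calls held without any single array. The calls lost without at least 1 array, with the highest adjusted p, were those of Cenpa (0.115), Acot1 (0.134), Cx3cr1 (0.119), Hspa2 (0.0733), Ccl11 (0.10), Junb (0.108), Rcan1 (0.0893) and Usp18 (0.0698).

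The effect of the TRAF2 transgene in the presence of the IkBa transgene was read from double transgenic against IkBaDN hearts. Dlg2 was the 1 probe called: it was detected on 0 IkBaDN arrays, had means of 7.79 ± 0.11 and 4.75 ± 0.10 (SD, n = 4 each) and was at least 4.39-fold higher (adjusted p = 7.06e-09). Relb had a log2 change of 0.28 ± 0.20 (adjusted p = 0.908) and Isg15 one of 1.95 ± 0.52 (adjusted p = 0.744). Isg15 had means of 8.13 ± 0.499 in double transgenic and 6.18 ± 0.463 in IkBaDN hearts (SD). Its SE comes from the fit of all 4 genotypes, and its SD was larger in TRAF2LC hearts (1.498). The large p therefore does not show that Isg15 was unchanged. Means were also higher for Ifit3 (8.93 against 7.38) and Rsad2 (9.69 against 8.62). They differed less for Usp18 (6.67 against 6.10) and Ifit2 (6.05 against 5.98). Irf7 was detected on 0 arrays of both genotypes. Components and targets of the non-canonical NF-kB branch rose as a list, 10 of 11 being higher (median 0.20, 0.13 without IkBaDN replicate 2 or double transgenic replicate 1, adjusted p = 0.0382; adjusted p = 0.381 with an estimated correlation). None passed over all genes tested and 2 rose adjusted over the list alone, and Map3k14 stood at 0.82 ± 0.26 (adjusted p = 0.807). In TRAF2LC against control the same list was not called (adjusted p = 0.215), with 6 of 11 members higher. Extracellular matrix genes rose, 18 of 23 being higher (median 0.17, adjusted p = 0.0428; adjusted p = 0.637 with an estimated correlation). Antigen presentation genes fell, 15 of 16 being lower (median -0.17, -0.07 without IkBaDN replicate 2 and -0.29 without IkBaDN replicate 3, adjusted p = 0.0428; adjusted p = 0.637 with an estimated correlation), although median scaling turned their median to 0.19, with the median of all probes at 0.35. In neither list did a member pass over all genes tested or adjusted over the list alone. At an unadjusted p under 0.05 there were 541 probes, where 472 would be expected by chance.

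The count of 1 probe was 3 with median scaling, 0 with detection on all 16 arrays, where Dlg2 was not tested, 2 with array weights, 2 with these 2 genotypes fitted alone, 4 without TRAF2LC replicate 4 and 2 without IkBaDN replicate 3. Without a filter none of the 3 lists was called (adjusted p = 0.198, 0.252 and 0.438 for extracellular matrix, antigen presentation and the non-canonical branch), the extracellular matrix call was lost without IkBaDN replicates 1 to 4 (adjusted p = 0.0838, 0.0748, 0.0826 and 0.118) and double transgenic replicates 3 and 4 (0.0694 and 0.224), the antigen presentation call without IkBaDN replicates 2 and 4 (0.457 and 0.179), double transgenic replicates 2 to 4 (0.0920, 0.114 and 0.144) and with the P number runs as a fixed block (0.889), and the non-canonical call without IkBaDN replicates 2 and 3 (0.101 and 0.127) and double transgenic replicates 3 and 4 (0.0656 and 0.0732).

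How far each transgene's effect differed with the other present was tested as an interaction. Tsc22d4 passed (log2 difference of effects -2.38 ± 0.23, SE, n = 4 per genotype, adjusted p = 1.42e-04): its means were 8.44 ± 0.25 in control, 10.90 ± 0.25 in TRAF2LC, 8.31 ± 0.27 in IkBaDN and 8.39 ± 0.19 in double transgenic hearts. The second probe that passed is unnamed here (probe ILMN_2889832, unnamed; interaction -3.02, adjusted p = 0.0010), with means of 6.01, 9.54, 6.13 and 6.64. Myh7 (-2.42 ± 0.55, adjusted p = 0.167), Tnip1 (-1.28 ± 0.27, adjusted p = 0.111) and Relb (-0.92 ± 0.29, adjusted p = 0.562) did not pass, nor did Usp18 (-1.92 ± 0.57, adjusted p = 0.455) or Tap1 (adjusted p = 0.282), detected on 0 control and 0 double transgenic arrays. In all, 2 probes were called, against 593 at an unadjusted p under 0.05.

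As lists, 8 of 31 were called in the interaction at the preset correlation, 0 with an estimated correlation and 1 with fry. The difference of effects had a median of -0.78 for interferon response genes (19 of 20 below 0, adjusted p = 7.77e-10; adjusted p = 0.259 with an estimated correlation) and of -0.60 for antigen presentation (16 of 16 below 0, adjusted p = 2.68e-09; adjusted p = 0.181 with an estimated correlation). Canonical NF-kB targets stood at -0.32 (adjusted p = 3.11e-04; adjusted p = 0.122 with an estimated correlation), macrophage markers at -0.43 (adjusted p = 1.06e-04; adjusted p = 0.181 with an estimated correlation) and the fetal gene programme and hypertrophy at -0.35 (adjusted p = 0.00686; adjusted p = 0.122 with an estimated correlation). Cell cycle genes stood at -0.19 (adjusted p = 0.019; adjusted p = 0.181 with an estimated correlation), smooth muscle and pericyte markers at 0.24 (adjusted p = 0.0253; adjusted p = 0.259 with an estimated correlation) and atrial cardiomyocyte markers at 0.35 (adjusted p = 0.00369; adjusted p = 0.259 with an estimated correlation). Without TRAF2LC replicate 4 the medians were -0.38 for the interferon response, -0.39 for antigen presentation, -0.26 for macrophage, 0.15 for smooth muscle and pericyte and 0.22 for atrial markers. The cell cycle median was -0.37 without control replicate 3 and -0.31 without TRAF2LC replicate 1, and the smooth muscle median 0.37 without TRAF2LC replicate 2. None of their members passed over all genes tested. Adjusted over the list alone, 2 canonical NF-kB targets, 3 antigen presentation genes, 1 gene of the fetal programme list and 2 macrophage markers passed with a difference below 0. The cell cycle call was lost without control replicate 1 (adjusted p = 0.0503) or double transgenic replicate 2 (0.0558), and the smooth muscle call without control replicate 4 (0.0839), TRAF2LC replicates 1 and 4 (0.0725 and 0.128), IkBaDN replicates 1 and 4 (0.10 and 0.0530) or double transgenic replicate 1 (0.0556), and with the P number runs as a fixed block (0.280), where the atrial call was lost too (0.0519). The count of 2 probes was 7 without TRAF2LC replicate 1, 11 without TRAF2LC replicate 4, 4 with median scaling, 5 with the authors' scaled values, 18 with array weights, 4 with the replicate block, 9 without the 2 arrays of lowest weight and 5 with the column sets as a block, both probes being among these 5.

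The probes called in each single transgenic comparison were followed into the comparison that shares no array with it. The 98 probes called in TRAF2LC against control had a mean change in the called direction of 1.12, and of 0.171 in double transgenic against IkBaDN hearts, 15.2% of the first, with 71 of 98 keeping their sign. The mean of 0.171 was above 0 for 16 of 16 pairs of arrays (two-sided exact permutation p = 0.0286, the smallest that 70 regroupings can give). With the runs of the P numbers as a block these means were 1.15 and 0.290. Single genes that differed strongly between double transgenic and IkBaDN hearts weigh much in the second mean. Among the 98, Dlg2 stood at 7.79 against 4.75, Isg15 at 8.13 against 6.18 and Ifit3 at 8.93 against 7.38. The value of 0.171 therefore does not show a change shared by all 98 probes. The 42 probes called in IkBaDN against control had a mean change of 1.04 there and 1.02 in double transgenic against TRAF2LC hearts, 98.1% of the first, with 40 of 42 keeping their sign (two-sided exact permutation p = 0.0286, again the smallest possible). Kcne1, Slc16a6 and Fam122b were among these 42, and 36 of the 42 were called in double transgenic against TRAF2LC hearts, all 36 in the same direction, where independent calls would give 0.618. Within the first 8 columns of the deposited table the means were 1.31 and 0.212 for the 98 probes and 1.0 and 1.05 for the 42, and within the last 8 columns 0.942 and 0.130, and 1.09 and 0.997.

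**Figure D3:**
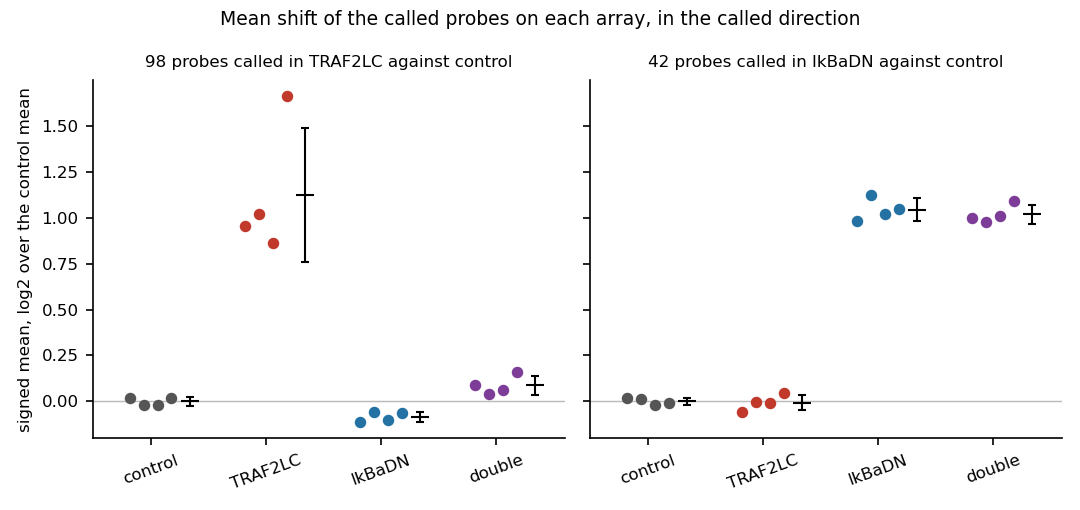
Mean change, in the called direction and as log2 over the control mean, of the 98 probes called in TRAF2LC against control (left) and the 42 called in IkBaDN against control (right) on each of the 16 arrays; each point is 1 array and the bar beside each group is the mean ± SD (n = 4). The 98 probes stood at 1.12 ± 0.36 in TRAF2LC and 0.09 ± 0.05 in double transgenic hearts, and the 42 probes at 1.04 ± 0.06 in IkBaDN and 1.02 ± 0.05 in double transgenic hearts.

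Over all 9449 probes the log2 changes of the TRAF2 transgene without and with the IkBa transgene correlated with r = 0.173 and rho = 0.143 (two-sided exact permutation p of r = 0.282). For the IkBa transgene without and with the TRAF2 transgene r was 0.353 and rho 0.269 (two-sided exact permutation p of r = 0.0441). These were the 2 correlations of this kind computed, and adjusted together their p values were 0.282 for TRAF2 and 0.0882 for IkBa, so neither passed. Both correlations run over probes, which are not independent replicates. The regroupings also mixed the first and last 8 columns of the deposited table, within which array deviations correlated at a mean of 0.204. Within the first and last 8 columns r was 0.133 and 0.110 for the TRAF2 transgene, and 0.185 and 0.265 for the IkBa transgene. With the runs of the P numbers in the labels as a block r was 0.306 and 0.305, and the unadjusted p of the IkBa transgene rose above 0.05 without control replicates 1, 2 and 4 (0.0547, 0.0555 and 0.0776), TRAF2LC replicates 2 and 3 (0.0710 and 0.0718), IkBaDN replicates 1 to 4 (0.0653, 0.0784, 0.0947 and 0.0547) or double transgenic replicate 4 (0.0645).

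**Figure D4:**
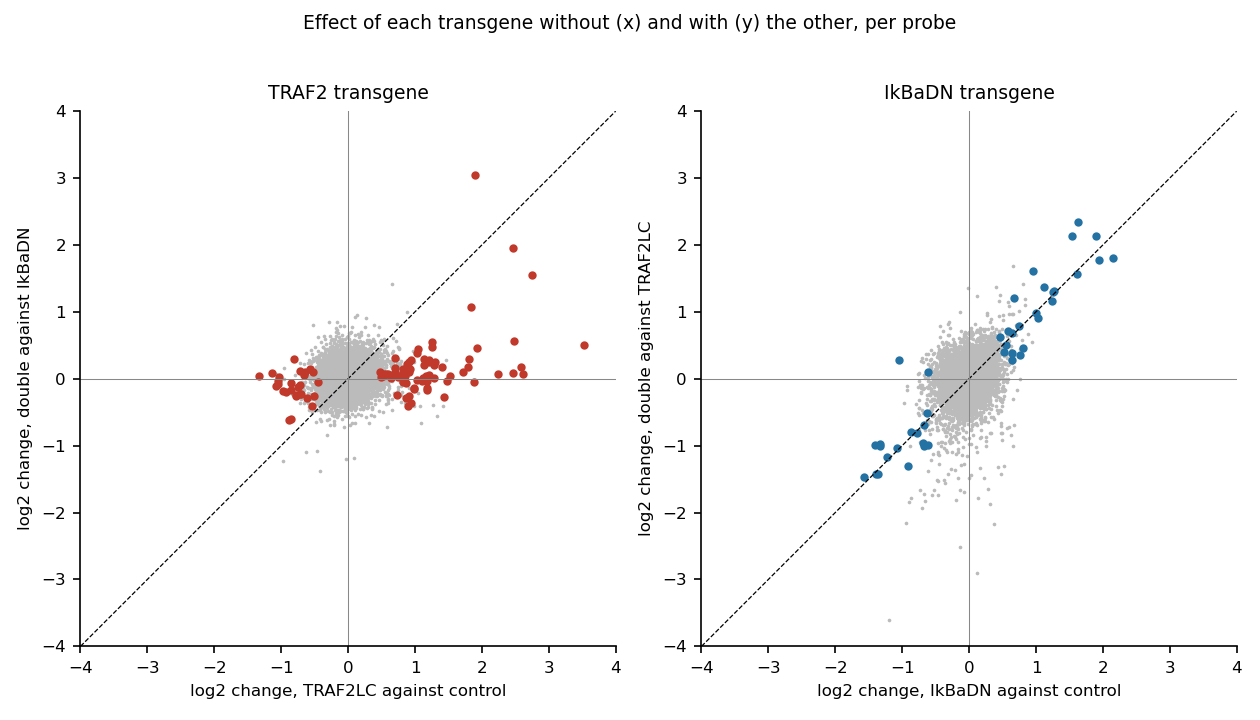
Log2 change of each of the 9449 probes for the TRAF2 transgene (left) and the IkBa transgene (right), without the other transgene on the x axis and with it on the y axis; grey points are probes not called on the x axis, coloured points the 98 and 42 called, and the dashed line marks equal changes. The coloured probes averaged 1.12 on the x axis and 0.171 on the y axis at left, and 1.04 and 1.02 at right, each in the called direction.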

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

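The tests of 1 array alone, of macrophages and of the Traf2 probe were chosen only after the results they address were seen. The counts of called probes were set beside every other split of the same arrays into 4 and 4 (35 splits). For TRAF2LC against control 1 split, the real one, called as many as 98 and the highest other called 2. For IkBaDN against control it was 1 of 35, with 42 against 1, and for double transgenic against control 1 of 35, with 86 against 0. For double transgenic against TRAF2LC it was 1 of 35, with 281 against 0. The share of 0.0286 is the smallest that 35 splits can give, and it was not adjusted over the comparisons. Differences between the real groups also widen the spread within the mixed splits. The real grouping thus called the most probes for these 4 counts, which does not exclude chance. For double transgenic against IkBaDN, 2 of 35 splits called at least 1 probe and the highest other called 3, so chance cannot be excluded for that count. For the interaction 4 of 100 splits, the real one among them, called at least 2, a share of 0.04. The highest other called 14, several times the real count, so chance is not excluded for that count either. Those splits mix all 4 genotypes, whose own effects stay open as a source of the 14 calls, untested.

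The 98 probes called in TRAF2LC against control, 66 of which moved back in double transgenic against TRAF2LC hearts, moved by a mean of 1.12 in the called direction without the IkBa transgene and by 0.171 with it. Regression of selected extremes is argued against: probes picked on the arrays of 1 set of 8 columns still moved by 0.713 and 0.960 in TRAF2LC against control on the other set, and by 0.0780 and 0.188 in double transgenic against IkBaDN, with the lowest array pairs of the former (0.610 and 0.632) above the highest of the latter (0.130 and 0.218). With the runs of the P numbers as a block the mean was 0.290 against 1.15. Double transgenic and IkBaDN arrays met only in the run with the lowest P numbers, so this cannot settle whether a difference in the runs contributed. Less TRAF2 transgene product in double transgenic hearts cannot be told apart from an effect of the IkBa transgene. The Traf2 probe differed by 0.26 in TRAF2LC against control without passing, so whether it reads the transgene is not known. How the IkBa transgene would act stays open and untested.

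Interferon response genes stood at a list median of 2.24 on TRAF2LC replicate 4, far from the other 3 TRAF2LC arrays; its first label number lies apart from the run of the other 15 arrays, and what that number stands for is not given in the sources used here. That array alone does not account for the increase, because the lowest of the other 3 was 0.594 and the highest control 0.0514. Background correction or normalization is argued against by the lowest median change over 5 other settings, 0.678. The macrophage markers rose less, with a highest median on those 3 arrays of 0.259, below 0.594. Medians of 2 different lists in whole tissue have no common scale, so more macrophages of an unaltered state are not excluded. Infiltrating cells with a high interferon response and a response of the heart cells stay open, untested.

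Of 68 groups of 4 values 7 held a value far from the rest, where chance alone gives about 3.4 (1 in 20). Besides the interferon response, antigen presentation genes stood at 1.27 and extracellular matrix genes at 0.56 on TRAF2LC replicate 4, apart from the other TRAF2LC arrays. On double transgenic replicate 1 antigen presentation genes stood at 0.25 and genes of the fetal programme and hypertrophy at -0.18, apart from the other double transgenic arrays. Extracellular matrix genes stood at -0.073 on control replicate 1, and macrophage markers at 0.22 on IkBaDN replicate 2, each apart from its group.

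The TRAF2 effect differed between hearts with and without the IkBa transgene, by the interaction test, for Tsc22d4 (-2.38) and for the unnamed probe (-3.02). At the preset correlation of 0.01 the lists called were the interferon response (median -0.78), antigen presentation (-0.60), macrophage markers (-0.43) and the fetal programme and hypertrophy (-0.35). Canonical NF-kB targets (-0.32), cell cycle (-0.19), smooth muscle and pericyte markers (0.24) and atrial cardiomyocyte markers (0.35) were called too. None of these 8 list interactions passed with an estimated correlation (adjusted p between 0.122 and 0.259).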

How the results depend on the processing

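The block of table columns and the fit without the 2 arrays of lowest weight (TRAF2LC replicate 4 and IkBaDN replicate 2) were chosen after the data were seen. No named call changed direction under any setting run, except that median scaling turned the median of antigen presentation genes between double transgenic and IkBaDN hearts to 0.19. Without background correction 38 probes were called in TRAF2LC against control and r of the IkBa effect was 0.288 (exact permutation p = 0.0563). With median scaling 18, 26, 3, 120 and 4 probes were called in IkBaDN against control, double transgenic against control, against IkBaDN, against TRAF2LC and the interaction, and r was 0.330 (exact permutation p = 0.0702). Cyclic loess gave an r of 0.351 (exact permutation p = 0.0531). The authors' scaled values gave 5 probes in the interaction, an r of 0.321 (exact permutation p = 0.0539) and 45 called lists. In TRAF2LC against control median scaling called 70 probes, 67 higher and 3 lower, and the authors' values 79, 70 higher and 9 lower; in IkBaDN against control the 18 called with median scaling were 7 higher and 11 lower. Of 111 results for named genes, calls ended for 39 with median scaling, 28 without background correction, 27 without a filter, 22 without the 2 arrays, 18 with the authors' values, 11 with the P number block, 6 with cyclic loess, 5 with normexp, 4 with the replicate block and 3 each with trended moderation, array weights and the random P number block, and for 36 of 109 with the compared groups alone. Relb in IkBaDN against control, not called, passed with the fixed (adjusted p = 0.00279, limma) and random P number blocks (0.0294) and the column block (0.0219). Without a filter 54 probes were called in TRAF2LC against control and r was 0.250 (exact permutation p = 0.0710). With detection on all 16 arrays, which leaves 6904 probes, 60 were called in TRAF2LC against control and 0 in double transgenic against IkBaDN, where Dlg2 was then not tested. Array weights gave 65, 168, 2 and 18 in IkBaDN and double transgenic against control, double transgenic against IkBaDN and the interaction. With the compared groups fitted alone, which leaves fewer arrays, 35, 24, 2 and 155 were called in TRAF2LC and IkBaDN against control and double transgenic against IkBaDN and TRAF2LC. The replicate block gave 4 and the column block 5 in the interaction, the P number block an r of 0.305, and leaving out the 2 arrays 57 in TRAF2LC against control and 9 in the interaction. With an estimated correlation 3 lists were called and with fry 15, 11 of them among the 29. Apart from the smaller sets of probes and arrays, the cause was not tested.

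Leaving out 1 array at a time, 40 to 99 probes were called in TRAF2LC against control, 21 to 45 in IkBaDN against control, 42 to 93 in double transgenic against control, 1 to 4 against IkBaDN, 184 to 305 against TRAF2LC and 2 to 11 in the interaction. The r of the TRAF2 effect ran from 0.117 to 0.206, that of the IkBa effect from 0.300 to 0.439, and the number of called lists from 26 to 38. Of 29 called lists 7 were lost without the 2 arrays of lowest weight: oxidative phosphorylation (adjusted p = 0.465, limma camera) and calcium handling (0.190) in TRAF2LC against control, the non-canonical (0.116) and antigen presentation (0.480) lists between double transgenic and IkBaDN hearts, and the cell cycle (0.103), smooth muscle (0.102) and atrial (0.0501) interactions. Of the 29, 3 were lost with the fixed P number block (antigen presentation between double transgenic and IkBaDN hearts, 0.889, and the smooth muscle, 0.280, and atrial, 0.0519, interactions), and 3 without a filter, all between double transgenic and IkBaDN hearts (non-canonical 0.438, antigen presentation 0.252, extracellular matrix 0.198). With the normalized values kept, 26 of 296 medians of called lists moved over 1.5 times without 1 array, 0 of them to the other sign. Of the named gene calls 67 of 103 held without any single array. Median scaling moved the median of the tested probes by 0.13, -0.23, 0.11, 0.35, -0.01 and 0.22 in the order of the comparisons above, and the authors' values by up to 0.11. Over the called lists and the 5 other background corrections and normalizations, 1 of 145 medians changed sign and 0 did so relative to that shift. Whether the replicate numbers pair the samples is not settled: deviations correlated at a mean of 0.154 within a number (16 of 24 pairs above 0.1, lowest -0.294) and -0.0515 between numbers, and 7 of 16 arrays were closest to one of their own number, so pairing was not assumed. Deviations correlated at a mean of 0.204 within the column sets and -0.204 between them. Deviations from the genotype means sum to 0 within a genotype. The values between numbers or sets thus largely follow from those within and add no evidence. All arrays of replicate 1 lie in 1 column set and all of replicate 3 in the other, so the groupings by number and by column are not separate. The other uncalled differences of Traf2, Nfkbia and Myh6 (14 in number) changed sign in 43 of 427 cases with 0 called. These differences were set apart after this was seen, and group means are given in their place. The slide block was not run, as the slide is not given in the sources used here. Signal near background limits the genes detected on 0 arrays of a group to lower bounds.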

Other observations

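The test of neighbouring genes was chosen only after the results were seen. Markers of cardiomyocytes, endothelial cells and fibroblasts were not called in TRAF2LC against control (medians of -0.07, 0.01 and 0.09, adjusted p = 0.955, 0.861 and 0.354), and 0 of their 31 measured members passed. Adipocyte markers had a median of -0.35 (adjusted p = 0.0901), 5 of 6 being lower, and 0 passed over all genes tested while 1 was lower adjusted over the list alone. Of the anti-apoptotic and cytoprotective genes, Bcl2 alone passed in TRAF2LC against control, and the list was not called (median -0.03, adjusted p = 0.624). Chemokines and cytokines were not called either (median 0.19, adjusted p = 0.532), with Ccl11 the 1 member past the threshold. Adjusted over the list alone, 1 cytoprotective gene rose, and 2 chemokine or cytokine genes rose and 1 fell.

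Heat shock genes were not called between double transgenic and TRAF2LC hearts (median -0.13, adjusted p = 0.0810), where Hspb6 and Hspa2 fell both over all genes and adjusted over the list alone. In double transgenic against control hearts the immediate early genes, which respond first to stimuli, had a median of -0.18 with 10 of 13 lower (adjusted p = 0.0521), 0 passed over all genes tested and 1 fell adjusted over the list alone. Genes of the circadian clock had a median of -0.25 there (adjusted p = 0.235) and 0 passed by either count.

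Chromosome segments that differ between the mice might be a candidate explanation for called genes such as Tsc22d4 and Dlg2, if called genes lay near one another. In TRAF2LC against control 10 pairs of called genes lay within 10 measured genes of each other, where random draws of as many genes gave a mean of 9.52 and a 95th percentile of 15. The pairs were 2 in IkBaDN against control (1.79 and 4), 9 in double transgenic against control (7.06 and 12) and 62 in double transgenic against TRAF2LC (76.3 and 91). The result was negative in all 4 comparisons: called genes as a set were not closer than random genes in 10000 draws over 6900 placed genes of GRCm38.p6, which does not exclude a segment behind single genes. Dlg2 itself lay 4 measured genes from the called gene Sytl2 in double transgenic against control hearts, where Dlg2 rose and Sytl2 fell. Slc17a7 lay next to the called gene Tead2 in IkBaDN and in double transgenic against control hearts. Other named genes had called neighbours too, among them Fam122b, 5 measured genes from Igsf1 in double transgenic against control hearts. In double transgenic against TRAF2LC hearts Kcne1 lay next to Rcan1, Hebp1 next to Emp1 and Myot next to Dpysl3.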
